A study of Homo sapiens with 12 samples.

How the data were processed

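Acetylated RNA immunoprecipitation sequencing (acRIP-seq) was carried out in HaCaT cells, an established line of human keratinocytes. RNA carrying N4-acetylcytidine (ac4C) is pulled down with an antibody in this assay, and the pulled-down fraction (IP) is sequenced beside the starting RNA (input). NAT10 is the enzyme that places ac4C on RNA. Per the labels, cells received an empty vector or a NAT10 overexpression construct, with 3 replicates of each, and an input and an IP library were made from each replicate, which gives 12 libraries. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether replicates were separate cultures, so p-values of tests over lists or libraries measure the spread between these samples, which may be technical. The adjusted permutation p-values of gene lists and pathways are taken over genes and do not measure that spread.

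Per the labels' protocols, total RNA was isolated with Trizol and libraries were made with a low-input whole-RNA kit. Per the submitters' processing notes, FastQC, cutadapt 1.9.3, HISAT2 2.0.4 and the GRCh38 genome build were used. The deposited files are 6 separate lists of peaks on mRNA, 1 for each replicate, with no pooled list used here. The peak names carry the name of the caller MACS, whose version is not given in the sources used here. Per the file headers, each peak has a score, which is the negative log10 of the authors' p-value times 10, a fold enrichment, which is a linear ratio of IP over background, a false discovery rate, and a length. The headers give no unit for the deposited false discovery rate, which was read as percent because its values run up to 100. The lowest score in any deposited list was 50, which is a p-value of 1e-05, and the lowest fold in any deposited list was 2. The authors' percent false discovery rate was 29.28 or higher for every peak. Read depth is unknown, since the lists give no read counts, and lists called separately can differ in length because libraries differ in depth. Fold and score are the authors' values and were used to describe, rank or filter peaks within a list. The median fold of each list was also compared between groups. In the deposited lists, 3 lines of control replicate 2 and 2 lines of overexpression replicate 2 were empty and were skipped.

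Start coordinates count from 0 in the deposited lists: 453 peaks had a start that, plus 1, was a RefSeq gene start, against 71 whose start itself was one. All coordinates are printed counting from 1. Of the 4373 peaks of control replicate 3 that overlapped a peak of overexpression replicate 2, 67.6% had both ends in common and 93.5% at least 1 end. Gene symbols are those of the files. Of 10870 genes with a peak in any list, 10600 had an identifier found in the RefSeq table of GRCh38.p14, and 349 of these have another symbol there. Exon, untranslated-region and genome sequence annotation was not used here, so the planned shares of peaks by transcript region and by sequence motif were not computed.

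Each list gave 1 value per replicate for the number of distinct peak intervals, the number of genes with at least 1 peak and the median of the fold on the log2 scale. Groups were compared by a two-sided exact permutation test over the 20 labelled splits of 6 lists, for which the smallest p is 0.1. Overlap between lists was the Jaccard index, the bases shared by a pair of lists over the bases covered by either. The mean over pairs within a group minus the mean over pairs between groups was tested one-sided over the 10 splits. For a single gene, a peak in 3 lists of one group and 0 of the other has an exact p of 0.1 by Fisher's test, so such genes were counted and set against the same count in the other splits.

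For gene lists, each gene received the number of overexpression lists with a peak minus the number of control lists with a peak. The mean over a list, minus the mean expected for genes with a peak in equally many lists, is called its lean. It was compared two-sided with 10000 random gene sets matched on that number, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Genes and not cultures are the units of this permutation test, so an exact permutation test over the 6 libraries is given beside it, of the log2 odds ratio of a peak in the genes of a list against the other genes with a peak in any list, with 0.5 added to each count. Of 24 pathway lists fixed before the data were examined, 22 had at least 5 genes with a peak and were tested. The minimum of 5 was set after the sizes were seen and left out the core histones, with 4 genes, and the mitochondrially encoded genes, with 0. The test was tested on simulated data with 200 lists of 25 genes drawn from the 10870 genes of the overexpression against control comparison. At an unadjusted threshold of 0.05 it called 3% of lists with no change. It called 45.5% of lists that lost 30% of their overexpression peaks and 94% of those that lost 60%. The simulated lists were random draws, so genes that gain or lose peaks together in a library were not simulated. The 3% therefore need not hold for the fixed lists.

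Genes were named by a rule fixed before the data were examined. It takes NAT10 and its partner THUMPD1, up to 12 genes with peaks in all lists of one group and no list of the other in each direction, ranked by the within-list percentile of their highest fold, 6 genes with peaks in all lists, and up to 4 members of each fixed list with the largest difference. Some genes that the rule takes are not reported here. Other genes named are said to have been chosen after their values were seen. Alternatives tried were a stricter fold of at least 4, an equal number of 3105 peaks from each list, each list left out in turn, the replicate number as a block, other definitions of overlap, presence at a common position, genes with a peak in at least 2 lists, and matching on the number of peaks in 5 bins. For the equal number, the peaks of highest score in each list were kept. Leaving out pairs of lists and matching on gene span in 5 bins were added after seeing the data. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used, with random seed 7.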

Results

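Peaks of acetylated RNA were compared between HaCaT keratinocytes carrying an empty vector and HaCaT cells overexpressing NAT10, the RNA cytidine acetyltransferase that makes ac4C. The study asked which genes differ with NAT10. Each group had 3 replicates, each with an IP and an input library, and each replicate gave 1 peak list. The lists held 4324, 19261 and 10838 peaks in control replicates 1, 2 and 3, and 12157, 12119 and 3105 peaks in overexpression replicates 1, 2 and 3, or 61804 peaks in all. Read depth is unknown for these lists. Read as percent, which its values imply, the authors' false discovery rate was under 5% for no peak of any list, and every peak of control replicate 1 and overexpression replicate 3 was listed at 100%.

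NAT10 itself carried at least 14 peaks in each overexpression list and at most 2 in each control list. The gene lies on chromosome 11 from 34105629 to 34146908 (GRCh38, gene identifier 55226). It had 14, 14 and 15 peaks in overexpression replicates 1, 2 and 3, against 1, 2 and 2 in control replicates 1, 2 and 3 (14.3 ± 0.58 against 1.67 ± 0.58, SD, n = 3 per group, exact permutation p = 0.1, the smallest this design allows). The peaks of the overexpression lists ran from 34108209 to 34146910, over 38.7 kb, and 13 of them had the same ends in all 3 overexpression lists. Equal ends need not mark a shared acetylation site. Over all genes, 93.5% of control replicate 3 peaks that overlapped one of overexpression replicate 2 shared an end. On NAT10, a peak of control replicates 1 and 2 at 34143445 to 34143528 had the ends of an overexpression peak. So did those at 34136642 to 34136775 in control replicate 2 and at 34135175 to 34135291 in control replicate 3. The authors' highest fold on the gene lay at 34143445 to 34143528 in all 3 overexpression lists, at 287, 31.6 and 46.4, while the highest folds in the control lists were 3.40, 4.91 and 5.01. No gene had more peaks than NAT10 in overexpression replicate 3, and 11 and 10 genes had more in overexpression replicates 1 and 2. THUMPD1, the adaptor that NAT10 uses to acetylate tRNA, had 1 peak, in control replicate 2, and none in the other lists.

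**Figure D1:**
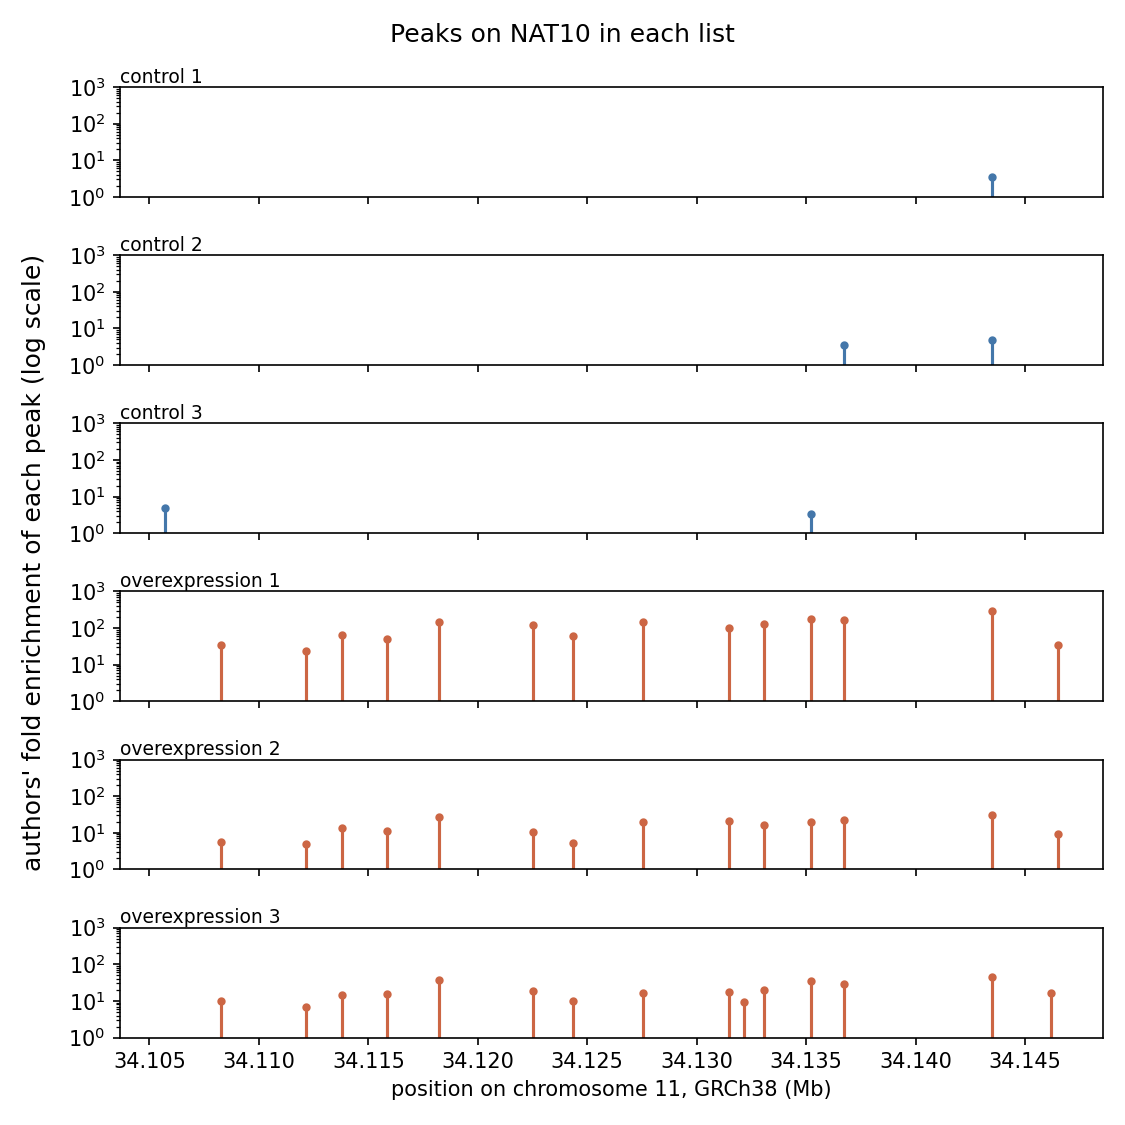
Peaks on NAT10 in the 6 lists: the x axis is the position on chromosome 11 in GRCh38 (Mb), the y axis the authors' fold enrichment (log scale), and each vertical line with a point is 1 peak at its midpoint. The overexpression lists have 14, 14 and 15 peaks along the gene and the control lists 1, 2 and 2, all of these with a fold of at most 5.01.

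Across all genes, NAT10 overexpression came with no detectable difference in how many mRNAs carried a peak. Genes with a peak numbered 3137, 7919 and 5956 in control replicates 1, 2 and 3 and 5798, 5949 and 2306 in overexpression replicates 1, 2 and 3. The group means were 5671 ± 2404 and 4684 ± 2061 genes (SD, n = 3 per group, log2 difference −0.30, exact permutation p = 0.5). Peaks numbered 11474 ± 7489 in control and 9127 ± 5215 in overexpression lists (SD, n = 3 per group, log2 difference −0.33, exact permutation p = 0.7). The direction of the difference in peaks depended on single lists: the log2 difference was 0.17 without control replicate 2 and 0.33 without overexpression replicate 3, and that in genes was 0.15 without overexpression replicate 3. The median fold was 6.88 ± 0.32 in control and 6.63 ± 0.50 in overexpression lists (SD, n = 3 per group, log2 difference −0.05, exact permutation p = 0.5). A test of 3 lists against 3 cannot give a p below 0.1.

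**Figure D2:**
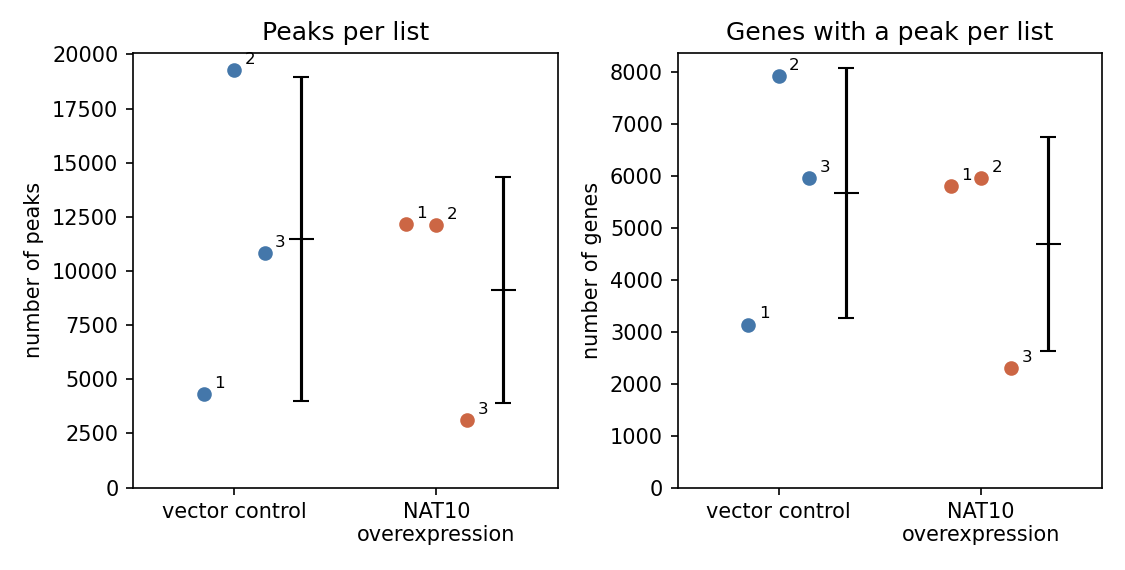
Number of peaks (left) and of genes with a peak (right) in each list, by group on the x axis: points are lists with their replicate number, and black bars are the group mean ± SD of 3 lists. Both groups span wide ranges that overlap, from 4324 to 19261 peaks in control and from 3105 to 12157 in overexpression.

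Of the 10870 genes with a peak, 677 had one in all 6 lists and 3110 in 1 list only. Those with the highest folds throughout included ERCC1, MTRNR2L12, SHF, the kinase gene AKT1 and SAPCD2. ERCC1 had the highest fold of its list in all 3 control lists, at 554, 511 and 822, and in overexpression replicate 3, at 539, and folds of 134 and 462 in overexpression replicates 1 and 2. Its top peak, at 45478736 to 45478828 on chromosome 19 in every list, lies outside the RefSeq span of ERCC1, which runs from 45407334 to 45451547. MTRNR2L12 is a nuclear copy of mitochondrial ribosomal RNA sequence, so its peak can hold reads of near-identical copies and is uncertain. Lists of the same group were not detectably more alike than lists of different groups: the mean Jaccard index was 0.165 within and 0.160 between groups (difference 0.00449, one-sided exact p = 0.5 over 10 splits). Overexpression replicate 3 had a mean index of 0.0494 with the other lists, against 0.146 to 0.214 for each of those lists, while 53.6% of its peaks overlapped a peak of another list, against 41.7% in control replicate 2 and 60.05% to 85.5% in the others.

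Peaks in all 3 overexpression lists and no control list were found on 29 genes. The 12 highest by fold included ZEB2, PAOX, ZBED1, RAB3IL1, ADAMTSL5, PPP2R1B, PSTK, LRRC37A3, BORCS5, ABCB8 and ZFP1. ZEB2, a transcription factor of epithelial-mesenchymal transition, had highest folds of 7.54, 18.2 and 14.4 in overexpression replicates 1, 2 and 3. PAOX, a polyamine oxidase, had 12.7, 6.39 and 45.0. The fixed list of extracellular matrix and epithelial-mesenchymal transition genes, which includes ZEB2, was not called (lean 0.00087). Of its 34 genes with a peak, 6 had peaks in more overexpression lists and 14 in more control lists. Only RAB3IL1 and KRT75, a keratin gene chosen after its values were seen, had a peak at a position common to all 3 overexpression lists, which takes the count from 29 to 2 genes. For 1 gene, 3 lists against 0 gives an exact p of 0.1 by Fisher's test, so no single gene passed a test. Among the 20 labelled splits of the 6 lists, 14 gave 29 or more such genes, the real one included, and the count was 62 without control replicate 3, 144 without control replicate 2, 75, 59 and 182 without overexpression replicates 1, 2 and 3.

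Peaks in all 3 control lists and no overexpression list were found on 118 genes. The 12 highest by fold were NOS3, ZNF575, DENND1B, UBAP1, MAPK10, FAM98B, BTBD11, ZC3H6, KCTD7, SSX2IP, GSAP and TCEAL3. NOS3, the nitric oxide synthase of endothelium, had folds of 17.2, 22.7 and 18.4 in control replicates 1, 2 and 3, with its top peak ending at 151002304 on chromosome 7 in each. ZNF575, a zinc finger gene, had 10.9, 30.0 and 17.9, and the kinase gene MAPK10 had 8.69, 40.6 and 15.03. Of the 118 genes, 57 had a peak at a position common to all 3 control lists. No single gene passed a test here either. Of the genes taken by the naming rule in both directions, 12 in each, 19 had a smaller difference with an equal number of peaks from each list. Among the 20 labelled splits, 5 gave 118 or more genes, the real one included, and the count was 526, 187 and 183 without control replicates 1, 2 and 3 and 269 and 322 without overexpression replicates 1 and 2.

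Genes of oxidative phosphorylation, ribosomes, translation, the proteasome and the stress response carried peaks in fewer overexpression lists, relative to control lists, than other genes with a peak in equally many lists. Of 22 fixed gene lists tested, 6 leaned to control past the adjusted threshold and 0 leaned to overexpression. An unadjusted permutation p under 0.05 was found for 7. Over all genes with a peak, the mean number of overexpression lists minus control lists was −0.27. Counts of members in more control lists hold this general tilt, while the lean is set against its expectation. Of 25 genes of oxidative phosphorylation, the respiratory chain and ATP synthase, with a peak, 22 had peaks in more control lists, 2 in more overexpression lists and 1 in equally many (lean −1.02, adjusted permutation p = 0.0022, the smallest that 10000 random sets and 22 lists can give). The list's genes with a peak numbered 4, 20 and 18 in control replicates 1, 2 and 3 and 3, 6 and 1 in overexpression replicates 1, 2 and 3. UQCRH and NDUFA8, subunits of respiratory complexes, had peaks in 3 control and 0 overexpression lists, and NDUFS6 and NDUFA10 in 3 and 1. Over libraries, the log2 odds ratio of a peak in genes of this list against other genes was 0.18 ± 1.02 in control and −2.30 ± 0.53 in overexpression (SD, n = 3 per group, exact permutation p = 0.1).

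Cytosolic ribosomal proteins had a lean of −1.01 (adjusted permutation p = 0.0176), with 8 of 9 genes in more control lists and RPS3 in 3 control and 0 overexpression lists. Only these 9 of the 79 genes in the fixed list had a peak in any list, so the lean does not describe the others. All 9 had a peak in control replicate 2, against 2 and 4 in control replicates 1 and 3 and 1, 1 and 2 in overexpression replicates 1, 2 and 3, and without control replicate 2 fewer than 5 genes were left and the list could not be tested. The call was lost without overexpression replicates 1 or 2 (lean −0.83 and −0.81, adjusted permutation p = 0.133 and 0.203) and with a fold of at least 4 (lean −1.16 over 5 genes, adjusted permutation p = 0.128). The proteasome, which degrades tagged proteins, had a lean of −0.69 (adjusted permutation p = 0.0176), with 17 of 22 genes in more control lists, and its base ATPase genes PSMC1 and PSMC4 had peaks in 3 control and 0 overexpression lists. All 22 had a peak in control replicate 2, against 8 and 11 in control replicates 1 and 3 and 8, 9 and 3 in overexpression replicates 1, 2 and 3. The adjusted permutation p missed the threshold without control replicates 1 or 2 (0.0517 and 0.356) and without overexpression replicates 1 or 2 (0.0851 and 0.0953), where the lean was −0.68, −0.61, −0.58 and −0.64.

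Ribosome biogenesis, which includes NAT10, had a lean of −0.46 (adjusted permutation p = 0.0176) and 32 of 46 genes in more control lists, with UTP14A in 3 and 0 and the nucleolin gene NCL in 3 and 1. Its lean turned to 0.0774, over 27 genes, with an equal number of peaks from each list, and the call was lost without control replicates 1 or 2 (lean −0.43 each, adjusted permutation p = 0.0524 and 0.235) and without overexpression replicates 1 or 2 (lean −0.45 and −0.31, adjusted permutation p = 0.0632 and 0.219). The unfolded protein and integrated stress response had a lean of −0.55 (adjusted permutation p = 0.0374) and 18 of 29 genes in more control lists, among them the chaperone gene DNAJA1 in 3 and 0. With 1 list left out it was called only without control replicate 1 (adjusted permutation p = 0.022, and 0.0632 to 0.158 for the others), with leans of −0.65 to −0.46. Translation factors had a lean of −0.56 (adjusted permutation p = 0.0429) and 20 of 25 genes in more control lists, such as EIF5B in 3 and 1, while EIF3H had peaks in 0 control and 2 overexpression lists. This call was lost whichever list was left out (lean −0.70 to −0.44, adjusted permutation p = 0.0632 to 0.21) and with a fold of at least 4 (lean −0.41, adjusted permutation p = 0.176). Control replicate 2, the longest list, had the most genes of these 3 groups, at 41, 26 and 21. Glycolysis and hypoxia genes, the other fixed list of energy metabolism, had a lean of 0.01 (adjusted permutation p = 1). Over libraries, 4 of the 6 lists were at the smallest exact permutation p of 0.1, and ribosome biogenesis and the cytosolic ribosomal proteins were at 0.2 and 0.3. Oxidative phosphorylation was called whichever list was left out, but the number of called lists was 3, 1 and 4 without control replicates 1, 2 and 3 and 1, 1 and 4 without overexpression replicates 1, 2 and 3. With an equal number of peaks from each list, 0 gene lists were called, and the leans of the 6 lists ran from −0.76 to 0.0774. Among genes with a peak in at least 2 lists only oxidative phosphorylation was called. Leans there were −0.65 for the proteasome, −0.59 for the stress response, −0.57 for translation factors and −0.45 for ribosome biogenesis. The cytosolic ribosomal proteins were not tested in that setting. Nor were they without control replicate 2 and overexpression replicate 3, where only oxidative phosphorylation was called. Leans were then −0.66 for the proteasome, −0.53 for the stress response and ribosome biogenesis and −0.51 for translation factors. Without control replicate 1 and overexpression replicate 3, only the stress response (lean −0.61) and translation factors (lean −0.48) lost their calls. Matching also on the number of peaks or on gene span kept all 6 calls.

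**Figure D3:**
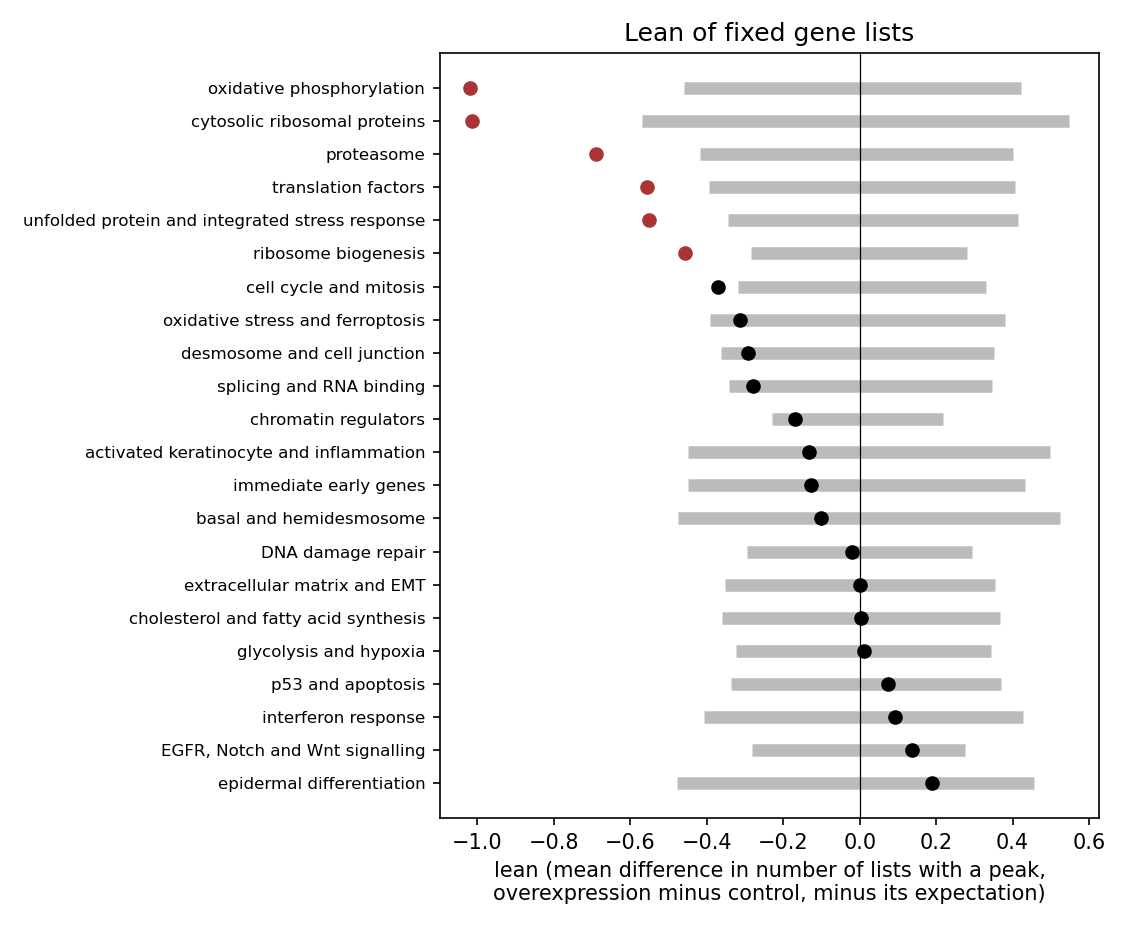
Lean of the 22 tested gene lists (points, with red for an adjusted p under 0.05) with the central 95% of 10000 matched random gene sets (grey bars): the x axis is the mean number of overexpression lists minus control lists with a peak, less its expectation, and the y axis names the list. The 6 red points lie at −1.02 to −0.46, left of their grey bars.

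Lists of keratinocyte genes did not pass the test. Desmosome and cell junction genes had a lean of −0.29 (adjusted permutation p = 0.309), with 17 of 28 genes in more control and 4 in more overexpression lists, among them the E-cadherin gene CDH1 in 2 control and 0 overexpression lists and TJP3 in 3 and 1. This lean was 0.0593 without control replicate 2 and overexpression replicate 3. Basal and hemidesmosome genes had a lean of −0.10 (adjusted permutation p = 0.971), with 9 of 16 genes in more control and 2 in more overexpression lists. Their mean difference was −0.44, against an expected −0.34. TP63, the transcription factor of basal keratinocytes, was in 2 control and 0 overexpression lists and KRT14 in 0 and 2. The KRT14 peaks were weak, with folds of 2.70 and 2.31 in overexpression replicates 1 and 2, near the lowest fold of 2 in any list. Epidermal differentiation genes had a lean of 0.19 (adjusted permutation p = 0.953), with 7 of 15 genes in more control and 6 in more overexpression lists, filaggrin (FLG) in 1 and 3 and involucrin (IVL) in 3 and 1. Activated keratinocyte and inflammation genes had a lean of −0.13 (adjusted permutation p = 0.971), with 10 of 19 genes in more control and 5 in more overexpression lists. S100A2, KRT6B and SLPI were each in 2 and 0, and RELB, a subunit of NF-kappa-B, was in 1 and 3. Each of these 3 leans changed sign: that of basal genes was 0.115 without overexpression replicate 3, that of differentiation genes −0.179 without overexpression replicate 2, and that of activated keratinocyte genes 0.107 with an equal number of peaks from each list. EGFR, Notch and Wnt signalling genes had a lean of 0.14 (adjusted permutation p = 0.806). Cell cycle and mitosis genes had a lean of −0.37, with CDC25A and CDK6 in 3 and 1, but missed the threshold (adjusted permutation p = 0.117). The 16 lists not called had leans of −0.37 to 0.19.

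Of the markers of other cell types, 3 of 9 melanocyte, 2 of 10 fibroblast, 3 of 8 endothelial and 1 of 12 immune cell genes had a peak in any list. For the keratinocyte lists these counts were 16 of 18 basal, 28 of 32 desmosome, 15 of 34 differentiation and 19 of 40 activated keratinocyte genes. Among melanocyte markers, MITF had a peak in overexpression replicates 1 and 2, SOX10 in overexpression replicate 1 and PMEL in control replicate 2. Fibroblast markers with a peak were COL1A1 in overexpression replicate 1 and PDGFRB in overexpression replicate 3. Endothelial CDH5 had a peak in all 3 control lists and overexpression replicate 2, VWF in control replicates 1 and 2 and overexpression replicate 1, and CLDN5 in overexpression replicate 1. The immune marker CD14 had 1 peak, in overexpression replicate 3.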

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

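Leaving out pairs of lists and matching on gene span were chosen after seeing the data, and the other alternatives before the data were examined. No alternative took the number of peaks, the number of genes or the median fold past a threshold, which 3 lists against 3 cannot pass. With 1 list left out, the log2 difference ranged from −0.91 to 0.33 in peaks and from −0.68 to 0.15 in genes. Without control replicate 2 and overexpression replicate 3, these differences were 0.83 and 0.44. The difference in Jaccard index within and between groups ranged from −0.0248 to 0.0371 with 1 list left out and was −0.00691 counted by genes. The cause was not tested.

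Genes in all overexpression lists and no control list numbered 35 to 182 with 1 list left out, 725 without control replicate 2 and overexpression replicate 3, 203 without control replicate 1 and overexpression replicate 3, and 2 at a common position. The counts for all control lists and no overexpression list were 134 to 526, 212, 610 and 57. Fewer lists loosen this criterion and a common position tightens it by construction.

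Called gene lists numbered 1 to 4 with 1 list left out, against 6. There were 4 at a fold of at least 4 and 0 at equal list size. There was 1 among genes in at least 2 lists and 1 without control replicate 2 and overexpression replicate 3. Matching on peak number or gene span kept all 6. Equal list size leaves fewer genes, 10 for oxidative phosphorylation. That list was called under 12 of 13 alternatives, with an adjusted p of 0.0021 to 0.651, the proteasome and ribosome biogenesis under 6 of 13, cytosolic ribosomal proteins under 6 of 10, the stress response under 4 of 13 and translation factors under 2 of 13. At equal list size the lean of ribosome biogenesis was 0.0774 and that of activated keratinocyte genes 0.107, which was 0.00982 among genes in at least 2 lists. Epidermal differentiation had −0.0324 and basal genes 0.0968 without control replicate 2 and overexpression replicate 3, and basal genes 0.0592 without control replicate 1 and overexpression replicate 3. With 1 list left out these 2 leans ranged from −0.179 to 0.557 and from −0.403 to 0.115. Glycolysis and hypoxia had −0.15 to 0.105 with 1 list left out, −0.0176 matched on the number of peaks, and −0.00248 and −0.172 without those pairs of lists. Desmosome and cell junction genes had 0.0593 without the first of those pairs. Of 16 lists not called, 13 changed direction under at least 1 alternative and 0 were called under any. Of the 1-group genes taken by the naming rule, 12 in each direction, 19 had a smaller difference at equal list size.

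Samples with the same replicate number had correlations of their deviations across genes of 0.000406, −0.0663 and −0.0649. Pairs with different numbers had −0.00549 to 0.0675. Over the pairings of each overexpression list these values nearly cancel, so they cannot tell whether the numbers pair the samples. The replicate block leaves the log2 differences unchanged by construction, at −0.33 for peaks, −0.30 for genes and −0.05 for fold (exact sign-flip p = 0.75 each). With this block 0 gene lists could be called, since the smallest p of 8 sign flips is 0.25. Equal list size fixes the number of peaks and gave no value for it. Every row of each list was a distinct interval, so counting every row could change nothing. Peak location and peak sequence were not run. Depth is unknown.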

Other observations

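The tests of the pathway labels, of a single library, of a swapped label and of splits were chosen only after the results were seen, and matching on gene span was added after seeing the data. Of the pathway labels carried in the authors' lists, 1 passed the threshold. Spliceosome genes, which remove introns, leaned to control among 215 labelled pathways with at least 15 genes (lean −0.50, adjusted permutation p = 0.0215): 60 of 84 genes had peaks in more control lists, 9 in more overexpression lists and 15 in equally many. Its genes with a peak numbered 36, 69 and 51 in control replicates 1, 2 and 3 and 40, 40 and 8 in overexpression replicates 1, 2 and 3. The adjusted p was 0.0932 without control replicate 1, 0.086 without control replicate 2 and 0.0537 without overexpression replicate 3, and ranged from 0.0215 to 0.249 over the alternatives. The fixed list of splicing and RNA binding genes was not called (lean −0.28, adjusted permutation p = 0.309). Nor did the authors' labels pass for groups whose fixed lists were called. Oxidative phosphorylation had a lean of −0.50 over 49 genes, the proteasome −0.80 over 20 and ribosome biogenesis −0.46 over 55 (adjusted permutation p = 0.0806 each), and the ribosome −0.49 over 29 (adjusted permutation p = 0.285). With 10 splits the share cannot go under 0.05, and the real split and 1 other gave 1 called pathway, the highest among the others being 1. No pathway leaned to overexpression past the threshold. At an unadjusted permutation p under 0.05, 13 pathways leaned to control and 6 to overexpression, among the latter tyrosine metabolism (lean 0.69, adjusted permutation p = 0.285).

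Of the housekeeping lists that leaned to control, explanations were weighed for oxidative phosphorylation only. Peaks with a fold under 4 are argued against as its sole source, since without them the lean was −0.88 (adjusted permutation p = 0.0022). At that fold translation factors (lean −0.41) and cytosolic ribosomal proteins (lean −1.16 over 5 genes) lost their calls. Weak peaks above that fold stay open, since the lists had median folds of 6.3 to 7.22. Peaks of low score also stay open, since the call was lost with only the 3105 peaks of highest score from each list. A single library is argued against, since the highest adjusted permutation p with 1 list left out was 0.0088. Gene length stays open: the lean was −1.03 (adjusted permutation p = 0.0022) when random sets were also matched on gene span, but this matching moved no tested list's lean by over 0.0424, and span counts introns and is not mRNA length, which was not measured. List length, which could follow from depth, also stays open, since at equal list size the lean was −0.56 with an adjusted permutation p of 0.651 over 10 genes. The real split gave 6 called lists (1 of 10 splits gave as many) and the highest other 2, too few splits for a share under 0.05, and oxidative phosphorylation itself was also called in 2 mixed splits, those with control replicates 2 and 3 beside overexpression replicate 3 (lean 0.80, adjusted permutation p = 0.0022) or overexpression replicate 2 (lean 0.67, adjusted permutation p = 0.0165). Lower mRNA levels of these genes, or a change of their acetylation under NAT10, may also account for the lean and were not tested.

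Overexpression replicate 3 had the lowest Jaccard index with the other lists. The share of its peaks that overlapped a peak of another list, 53.6%, was above the 41.7% of control replicate 2, the longest list. It was below the 60.05% to 85.5% of the others, of which control replicate 1, the next shortest list, had 85.5%. The small number of peaks of overexpression replicate 3 is argued against as the whole cause of the low index. With the 3105 peaks of highest score from each list its mean Jaccard index was 0.0584, against 0.128 for the next lowest list. That setting kept every peak of this list, weak ones included, and did not make the bases covered equal. All peaks of this list covered 586 kb, against 1494 kb in control replicate 1. An effect of few bases or of weak peaks therefore stays open. A swapped label is argued against, since this list had 15 NAT10 peaks, against at most 2 in a control list. Low depth or quality of this library may remain a cause, and neither was measured. No biological explanation was tested.

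NAT10 had many high peaks in the overexpression lists. Short peaks with unstable folds are argued against: among peaks of like length in the same list, the lowest of the 3 median percentiles of NAT10's folds was 90.6, close to the bound of 90 set for the test. RNA made from the overexpression construct is a candidate source of these peaks, as is acetylation of NAT10's own mRNA, and the lists do not separate them.

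Among the labelled splits of the 6 lists, 14 of 20 gave at least as many genes as the 29 in all overexpression lists and no control list, and 5 of 20 at least as many as the 118 in the other direction. The highest other split gave 428 genes, those with a peak in control replicate 2 and overexpression replicates 1 and 2 alone. These counts were not adjusted for list length, and that split joins lists of 7919, 5798 and 5949 genes. With 20 labelled splits the share cannot go under 0.05.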
